A study of Arabidopsis thaliana with 24 samples.

How the data were processed

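Expression was measured in 24 samples of Arabidopsis thaliana seedlings with the roots removed, 1 sample per one-colour array. Total RNA had been extracted with the RNeasy plant kit with a DNase step, and amplified and labelled with biotin by the MessageAmp II-Biotin kit, which copies RNA from a primer that binds poly(A) tails. The control probe sets carry Affymetrix names. A probe set is a group of short probes that together measure 1 transcript. The values used here are the authors' deposited intensities, 1 per probe set and array, on a linear scale. The submitters' processing notes name GCRMA, affy and limma, without a role, an order or a version; GCRMA is a method that corrects background by probe sequence, normalizes arrays to each other and summarises the probes of a probe set. The array design, the background settings and any filter on probe sets are not given in the sources used here.

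The values of the 3 h arrays and of the 1 week arrays differ in rounding and in level. Mean intensity lay between 463 and 496 on the 12 arrays of 3 h and between 583 and 602 on the 12 arrays of 1 week, and the medians between 45.8 and 54.6 and between 47.2 and 62.6. The 2 time points therefore appear to have been normalized separately, and no level was compared between them directly; the comparisons of time with phosphate set a difference within 1 time point against a difference within the other. The lowest value was 2.5 at 3 h and 2.51 at 1 week, and the highest 42832 and 49125. Between 53.1 and 55.0% of the probe sets lay above 5 on the log2 scale on each array. The lowest correlation of log2 values between 2 arrays of a group was 0.979 at 3 h and 0.978 at 1 week. Arrays give no count of molecules, and their number limits the precision.

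Groups were taken from the sample titles: 2 genotypes, 2 media and 2 times make 8 groups of 3 arrays, and the series design states that the 3 are biological replicates of at least 4 seedlings each. The titles also number the replicates. Whether arrays with the same number belong together is not stated, so the number was tested on the data. Within a comparison, the deviations of each array from its group mean were correlated with those of the array of the same number in the other group. The arrays are called paired here only where all 3 correlations exceeded 0.1. The main fit ignores the pairing. A fit with the replicate number as a block was run for every comparison, paired or not.

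Intensities were turned into log2 with no pseudocount. Of 22810 probe sets, 64 Affymetrix controls were left out and 22746 were fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with default settings), with 1 mean for each of the 8 groups, so that all arrays share 1 estimate of the spread. The fit had 16 residual and 1.40 prior degrees of freedom. The p-values were two-sided and adjusted by Benjamini and Hochberg's method over all fitted probe sets of a comparison, and an adjusted p under 0.05 is called past the threshold. Tests were 8 comparisons of 2 groups, -P against +P and pnp1-1 against WT in each setting, and 4 comparisons of differences, genotype by phosphate at each time and time by phosphate in each genotype. Changes are log2 differences with limma's standard error (SE), group levels are means with the standard deviation (SD) over the 3 arrays, and a change of 1 is a 2-fold difference.

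Probe sets were named through the platform annotation and the gene table of assembly TAIR10.1, of which only names and gene order were used. No gene was given for 8730 of the fitted probe sets, exactly 1 for 13513 and several for 503; a probe set without a name here is not one without a gene. Of the probe sets with 1 gene, 13436 matched the gene table by identifier. In all, 77 probe sets were plastid-encoded. Of these, 8 list several genes, the copies of 1 plastid gene, and stand outside the probe sets with 1 gene. Another 23 had no match by identifier and were taken as mitochondrion-encoded by their gene symbol. The gene disrupted in the mutant was among the genes with no named probe set, and its level was not analysed here.

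The rule for naming genes was fixed before the data were examined. In each comparison it takes up to 10 probe sets with the largest rise and up to 10 with the largest fall among those past the threshold with exactly 1 gene, a mean of at least 5 (log2) in the group where it is highest and, between 2 groups, no overlap between the arrays; 10% of probe sets separate in this way by chance with 3 arrays against 3. It adds up to 4 members past the threshold from each gene list and, where nothing passes, the 3 smallest p. A gene with several probe sets is given by the one with the highest mean. The rule also allows members that define a list to be given as values when they do not pass, without saying which. List members that did not pass are given in the Results with their adjusted p, and the choice of them was not fixed beforehand. Other names outside the rule are marked there as chosen after their values were seen.

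The 20 gene lists were also fixed before the data were examined. Of their 393 genes, 49 had a named probe set: 11 nuclear photosynthesis genes, 7 root markers, 5 of anthocyanin synthesis, 4 of senescence, 3 each of starch and sugar, sulfate, nitrate and glucosinolate metabolism, 2 each of jasmonate and iron, and 1 each of phosphatases, membrane lipids, chloroplast RNA, plastid ribosomal proteins, oxidative stress and the clock. Phosphate signalling, phosphate transporters, salicylic acid defence and floral transition had 0 measured members. Lists of at least 3 members, a minimum set once the annotation had been seen, and the plastid- and mitochondrion-encoded probe sets make 10 lists, each tested in 12 comparisons with limma's camera at a preset correlation of 0.01, which asks whether a list shifts relative to all other probe sets; p-values were adjusted over the lists of a comparison. Camera with a correlation estimated from the data, and fry, were run beside it. Fry's p asks whether the members move, on balance, 1 way, and does not compare them with other genes.

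Alternatives were a filter that keeps 13555 probe sets above 5 (log2) on at least 3 arrays, quantile normalization, eBayes with a trend and robust settings, array weights, the replicate number as a block, a fit of the compared arrays alone, and leaving out each array in turn. Added after the data were seen were a fit of the arrays of 1 time point, a block over the compared arrays alone, gene families by symbol and a list of genes induced by mitochondrial dysfunction. Array weights were computed gene by gene, since the default method did not converge. The fit was tested on simulated data with 22746 probe sets, 100 of them changed by 1 and 100 by 2 on the log2 scale. For 1 comparison of 2 groups it recovered 56 and 89 of them, with 7 false calls among 152, and for the difference of differences 42 and 75, with 12 false calls among 129. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.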

Results

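Gene expression was compared between wild-type Arabidopsis thaliana (WT, Columbia) and pnp1-1, a null mutant of the chloroplast polynucleotide phosphorylase. This enzyme (PNPase) is an exoribonuclease that trims the ends of chloroplast RNAs and degrades them. Seedlings were raised for 2 weeks on MS medium, a standard plant nutrient medium, and then moved to fresh medium. It held phosphate (+P), or potassium phosphate was left out, with potassium sulfate in its place (-P). Shoots, that is seedlings freed of their roots, were collected 3 h or 1 week after the transfer. Each of the 8 groups had 3 one-colour Affymetrix arrays, each from a separate biological replicate of at least 4 seedlings, and 22746 probe sets were tested with limma. Values are log2 intensities. Those near 2 lie close to the lowest of the table, and a fold change against such a level depends on the background correction. Because the labelling kit starts from poly(A) tails, values of plastid-encoded genes are read here as those of the polyadenylated part of their transcripts, and starts at internal runs of A were not tested.

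After 1 week without phosphate, 423 probe sets rose and 358 fell in WT shoots. Among probe sets with exactly 1 named gene, the largest rise was in AT5G20790, a protein of unknown function, at 12.66 ± 0.50 on -P and 3.97 ± 0.25 on +P (SD, n = 3), a change of 8.69 ± 1.01 (SE). AT1G08310, an alpha/beta hydrolase, rose by 7.56 ± 0.61, and PRX52, a cell wall peroxidase, by 7.20 ± 1.12 (SE, n = 3 per group). The purple acid phosphatase AT1G13750 (PAP1), the 1 measured member of the phosphatase list, rose by 5.28 ± 0.52. FHL, a partner of phytochrome A in light signalling, rose by 5.35 ± 0.22 and AT5G09570, a small cysteine-rich mitochondrial protein, by 6.25 ± 0.39. The adjusted p of these 3 were 7.2e-06, 8.7e-11 and 2.5e-08. Among the genes that fell, the glutaredoxin AT3G62950 changed by -4.19 ± 0.85 and AT1G47400, a short peptide that promotes iron uptake, by -5.38 ± 1.32 (adjusted p = 0.0104 and 0.0305). AT1G73600 (NMT3), a methyltransferase of phosphatidylcholine synthesis and the 1 measured gene of the membrane lipid list, changed by -2.55 ± 0.64 (adjusted p = 0.0359). The stress regulator STZ (ZAT10) rose by 1.92 ± 0.46 and the plastid ribosomal protein AT2G43030 (PRPL3) changed by -0.41 ± 0.10 (adjusted p = 0.0259 and 0.0271).

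Of the 77 plastid-encoded probe sets, 4 fell and 0 rose in WT after 1 week on -P, and 14 fell when adjusted over the list alone. The photosystem genes psbA, psbZ and psaC changed by -1.10 ± 0.30, -0.78 ± 0.15 and -0.97 ± 0.21 (SE, n = 3 per group), and ndhI of the NADH dehydrogenase-like complex by -0.45 ± 0.11. The median of the list was -0.49 (camera adjusted p = 5.9e-12; adjusted p = 0.325 with an estimated correlation, 0.0308 by fry). Root markers, genes typical of root cells, had a median of 0.14 and a camera call upward (adjusted p = 0.0190; 0.325 with an estimated correlation, 0.0308 by fry), with 0 of 7 past the threshold and 2 when adjusted over the list alone. The highest change was 1.28 ± 0.36 for the root peroxidase PER57, at 3.42 on -P (adjusted p = 0.0626). None of the 5 anthocyanin synthesis genes passed the threshold (0 also when adjusted over the list alone). Their median was 1.63 (camera adjusted p = 0.0520; 0.0175 with the block; adjusted p = 0.390 with an estimated correlation), and DFR, dihydroflavonol reductase, had a change of 3.88 ± 2.13 that did not pass (adjusted p = 0.429). No member of the nuclear photosynthesis, starch and sugar, senescence, sulfate, nitrate, glucosinolate or mitochondrion-encoded lists passed the threshold in this comparison. Adjusted over the list alone, 2 of 3 starch and sugar genes (median 1.22) and 1 of 3 sulfate genes rose, and no member of the others passed. The jasmonate-responsive defence genes PDF1.2 and THI2.1 had changes of 2.84 ± 0.97 and 2.43 ± 1.05 that did not pass (adjusted p = 0.127 and 0.258). The iron regulators BHLH101 and PYE, with -3.62 ± 1.56 and -1.90 ± 0.75, did not pass either (adjusted p = 0.256 and 0.201). The organelle RNA polymerase RPOTMP and the clock gene GI had changes of -0.19 ± 0.37 and -0.45 ± 0.80 (adjusted p = 0.905 for both).

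The total of 781 probe sets in WT at 1 week depended on single arrays: it was 1273 without +P replicate 1, 276 without +P replicate 2, 331 without +P replicate 3 and 476 without -P replicate 3. It was 298 in a fit of the 6 compared arrays alone, 25 with a block in that fit and 4068 with array weights. The calls for AT5G20790, AT1G08310, PRX52, AT1G13750, FHL, AT5G09570 and psbZ passed without each of the 6 arrays. That for AT3G62950 ended without +P replicate 2 (adjusted p = 0.0587). With the 6 arrays left out in turn, AT1G47400, AT1G73600, STZ, AT2G43030, psbA, psaC and ndhI lost their calls without 4, 5, 5, 4, 5, 1 and 3 of them. Their adjusted p then reached 0.160, 0.134, 0.120, 0.140, 0.184, 0.0608 and 0.145.

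**Figure D1:**
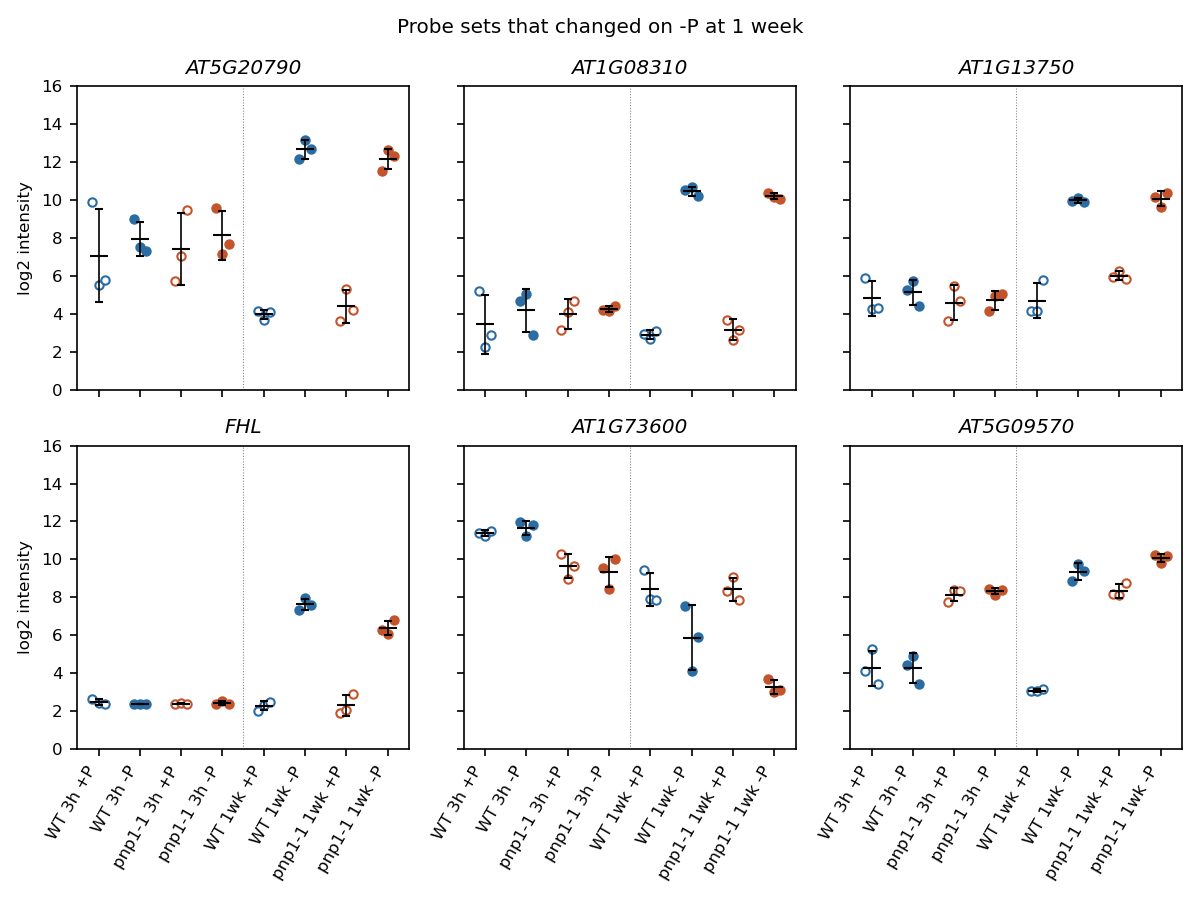
Log2 intensity (vertical axis) of 6 named probe sets on each of the 24 arrays, grouped by genotype, time and medium along the horizontal axis, with open circles for +P, filled circles for -P, and bars for the group mean and SD (n = 3). AT1G13750 stood at 9.97 ± 0.11 on -P and 4.69 ± 0.94 on +P in WT at 1 week, and at 10.06 ± 0.38 and 6.01 ± 0.23 in pnp1-1.

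In pnp1-1, 186 probe sets rose and 28 fell after 1 week on -P. AT5G20790 rose by 7.77 ± 1.01 and AT1G08310 by 7.05 ± 0.61 (SE, n = 3 per group), the largest rises among named genes in the mutant too. Further rises were those of AT2G04460 with 6.36 ± 0.55 and AT1G26390, an FAD-linked oxidase of the berberine bridge enzyme family, with 5.87 ± 0.72 (adjusted p = 2.0e-06 and 0.000134). AT1G13750 (PAP1) rose by 4.05 ± 0.52 (adjusted p = 0.000209). NMT3 (AT1G73600) had the largest fall past the threshold, from 8.42 ± 0.61 on +P to 3.29 ± 0.36 on -P (SD, n = 3), a change of -5.13 ± 0.64 (adjusted p = 0.000181). The cell wall invertase family member cwINV6 changed by -2.25 ± 0.23 and the glycosyltransferase UGT71C2 by -1.81 ± 0.26 (adjusted p = 1.4e-05 and 0.000575).

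No member of the 10 tested lists passed the threshold in pnp1-1 at 1 week. Adjusted over the list alone, 1 plastid-encoded and 1 nitrate response probe set rose. The plastid-encoded probe sets had a median of 0.07 and a camera call upward (adjusted p = 0.00910; adjusted p = 0.929 with an estimated correlation, 0.904 by fry, 0.0748 after the filter on low values). The arrays of this comparison counted as paired by replicate number (correlations of 0.12 to 0.80), which the fit behind the 214 calls ignored. Only 2 of the 6 arrays correlated best with the array of their own number, so this pairing is uncertain. The total of 214 probe sets was 126 in a fit of the 6 compared arrays with a block and 2945 with array weights. Leaving out 1 array gave 163 to 253. Of the 21 genes that the rule names in this comparison, PRX52, AT5G48430, AT3G19550, AT3G55840 and AT3G56360 lost their calls without single arrays. This held for 5, 6, 6, 4 and 3 of the 6 arrays (adjusted p up to 0.209, 0.202, 0.174, 0.118 and 0.0888).

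At 3 h, limma called 0 probe sets between -P and +P in WT and 2 in pnp1-1. The smallest p in WT belonged to AT1G19320, SRC2, a cold-responsive gene, and AT1G23790, with changes of 0.74 ± 0.11, 0.98 ± 0.16 and 1.54 ± 0.27 (SE, n = 3 per group; adjusted p = 0.0867, 0.0867 and 0.106). An unadjusted p under 0.05 was found for 817 probe sets in WT and 283 in pnp1-1, where chance gives 1137 over all probe sets. These numbers come from a fit without the pairing of the arrays described next, and with the block they were 1219 and 631. The 2 called in pnp1-1, chosen after their values were seen since the rule for naming excludes dim probe sets, were a probe set without a named gene, at 2.66 ± 0.03 and 2.15 ± 0.15 (SD, n = 3), and AT1G49700, at 2.81 ± 0.07 and 2.43 ± 0.00. Their adjusted p were 0.00310 and 0.0116. No member of a tested list passed in either genotype. Plastid-encoded probe sets had a median of 0.17 in pnp1-1 with a camera call upward (adjusted p = 4.8e-06; adjusted p = 0.975 with an estimated correlation, 0.996 by fry) and 0.03 in WT with none (adjusted p = 0.782).

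The replicate numbers paired the arrays in both comparisons at 3 h, with correlations of the deviations of 0.50 to 0.73 in WT and 0.24 to 0.46 in pnp1-1. With the block limma called 4 and 1 probe sets. In WT the count was also 1 after quantile normalization, 1 with trend and robust settings and 6 with array weights. It was 17, 6 and 8 without +P replicates 1, 2 and 3, and 3, 1 and 3 without -P replicates 1, 2 and 3. In pnp1-1 it was 0 after the filter on low values, 0 in the fits of the compared arrays alone, with or without a block, and of the 3 h arrays. It was 1 without +P replicate 2, +P replicate 3 or -P replicate 2. AT1G49700 lost its call without 4 of the arrays (adjusted p up to 0.104).

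**Figure D2:**
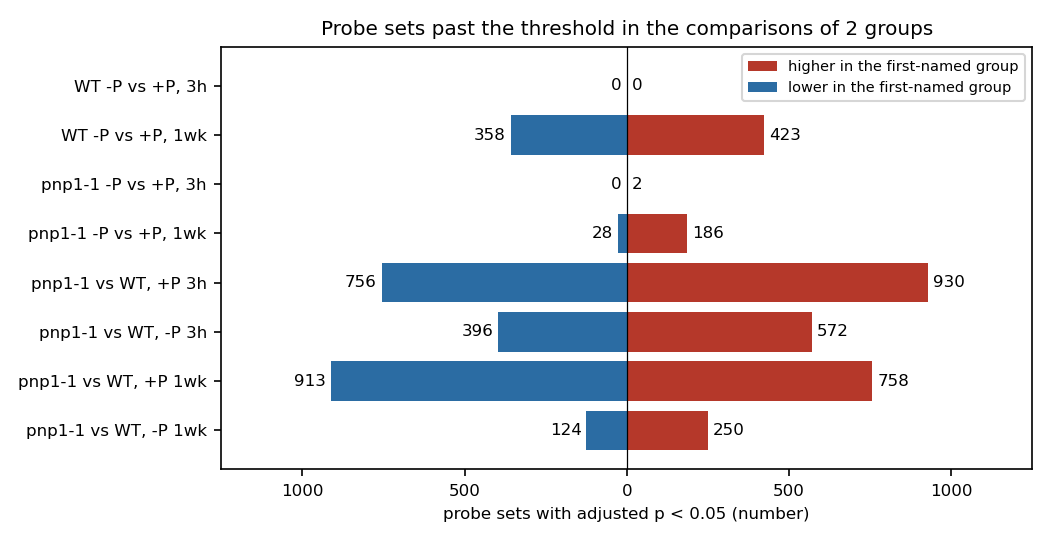
Number of probe sets with an adjusted p under 0.05 (horizontal axis) in each of the 8 comparisons of 2 groups, with those higher in the first-named group to the right and those lower to the left. The 4 genotype comparisons held 1686, 968, 1671 and 374 probe sets and the 2 phosphate comparisons at 3 h held 0 and 2.

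The genotypes differed in each setting. At 3 h on +P, 930 probe sets were higher and 756 lower in pnp1-1 than in WT. Among nuclear genes, the peroxidase AT5G39580 was higher by 5.13 ± 0.94, the calmodulin-like gene CML41 by 5.01 ± 0.91 and the osmotin-like gene OSM34 by 4.52 ± 0.60 (SE, n = 3 per group; adjusted p = 0.00308, 0.00288 and 0.000312). The beta-1,3-glucanase AT4G16260 was higher by 4.46 ± 0.64 and GAT1_2.1, a glutamine amidotransferase, by 4.98 ± 0.92 (adjusted p = 0.000590 and 0.00328). Lower in the mutant were AT1G13650 with -6.33 ± 1.12 and the glutaredoxins AT2G47880, with -6.02 ± 0.70 from a WT level of 8.12 ± 0.52 (SD, n = 3), and AT1G06830, with -3.71 ± 0.71 (adjusted p = 0.00245, 0.000101 and 0.00416). PYK10, a beta-glucosidase of endoplasmic reticulum bodies that is abundant in roots, stood at 12.20 ± 0.63 in pnp1-1 and 10.39 ± 0.37 in WT (SD, n = 3; adjusted p = 0.00442).

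Of the 11 nuclear photosynthesis genes, 5 fell and 0 rose in pnp1-1 at 3 h on +P, and 7 fell when adjusted over the list alone. The photosystem I subunits PSAE-1 and PSAN changed by -0.72 ± 0.14 and -0.93 ± 0.22, the photosystem II subunit PSBW by -0.65 ± 0.13 and the antenna protein LHCB4.1 by -0.45 ± 0.11 (SE, n = 3 per group). The median was -0.65 (camera adjusted p = 8.4e-07; adjusted p = 0.245 with an estimated correlation, 0.0105 by fry). Starch and sugar genes had a median of -0.98 with 0 of 3 past the threshold and 3 lower when adjusted over the list alone (camera adjusted p = 0.0266; adjusted p = 0.245 with an estimated correlation, 0.0159 by fry). Among 4 senescence genes WRKY6, a transcription factor, rose by 1.89 ± 0.48, with 2 up when adjusted over the list alone and no camera call for the list (adjusted p = 0.168; 0.0159 by fry). PRPL3 (AT2G43030) changed by -0.44 ± 0.10 (adjusted p = 0.0105). The 1686 calls fell to 694 without WT replicate 3 and 1117 without pnp1-1 replicate 2, to 161 in a fit of the 6 compared arrays alone and to 0 with a block in that fit. They rose to 2551 with array weights. With 1 array left out at a time, PSAN, LHCB4.1, WRKY6 and AT2G43030 lost their calls for 3, 3, 3 and 2 of the 6 arrays (adjusted p up to 0.0723, 0.0816, 0.108 and 0.0683). LHCB4.1 did so after quantile normalization too. The other genes given here for this comparison passed without each single array, but not in the fit with 0 calls.

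At 3 h on -P, 572 probe sets were higher and 396 lower in pnp1-1. The lectin gene AT1G52100 was higher by 5.30 ± 0.44, the defensin-like gene PDF1.4 by 5.20 ± 0.91, AT3G20370, which encodes a TRAF-like protein, by 5.13 ± 0.71, and AT2G21640 (UPOX), a mitochondrial protein induced by oxidative stress, by 4.41 ± 0.40 (SE, n = 3 per group; adjusted p = 2.4e-06, 0.00324, 0.000474 and 7.3e-06). AT2G47880 changed by -5.15 ± 0.70 and AT4G12980 by -4.62 ± 0.83 (adjusted p = 0.000362 and 0.00390). PYK10 was higher by 2.39 ± 0.35 (adjusted p = 0.000672). Of the nuclear photosynthesis genes, 2 of 11 fell, LHCB4.1 with -0.48 ± 0.11 and the ATP synthase subunit ATPC1 with -0.43 ± 0.10. When adjusted over the list alone 7 fell. The median was -0.44 (camera adjusted p = 2.4e-06; adjusted p = 0.351 with an estimated correlation, 0.0576 by fry). With the block 5 fell (0.0170 by fry). The arrays of this comparison paired, as given below, but the block was fitted over all arrays, also those that did not pair. Starch and sugar genes had a median of -0.89 with 0 of 3 past the threshold and 2 lower when adjusted over the list alone (camera adjusted p = 0.0276; adjusted p = 0.351 with an estimated correlation, 0.0684 by fry), and with the block 1 fell (0.0170 by fry). The replicate numbers paired these arrays (correlations of 0.17 to 0.39). With the block over all arrays 1585 probe sets passed instead of 968. The count was 607 and 462 without WT replicates 2 and 3, 558 and 425 without pnp1-1 replicates 1 and 2. It was 420 in a fit of the compared arrays alone, 145 with a block in that fit and 3197 with array weights. LHCB4.1 and ATPC1 lost their calls without single arrays, each for 4 of the 6 (adjusted p up to 0.0810 and 0.116), LHCB4.1 after quantile normalization too.

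After 1 week on +P, 758 probe sets were higher and 913 lower in pnp1-1. AT3G20370 was higher by 6.39 ± 0.71, AT5G09570, the mitochondrial protein that rose on -P in WT, by 5.26 ± 0.39, and the copper protein ARPN (plantacyanin) by 5.09 ± 0.64 (SE, n = 3 per group; adjusted p = 4.1e-05, 5.6e-07 and 0.000123). AT2G32020, an N-acetyltransferase, was higher by 4.55 ± 0.29 and AT1G52100 by 4.64 ± 0.44 (adjusted p = 7.6e-08 and 7.0e-06). PYK10 reached its largest difference, 3.46 ± 0.35, with 13.35 ± 0.12 in pnp1-1 and 9.89 ± 0.23 in WT (SD, n = 3; adjusted p = 1.4e-05). The glutaredoxins AT1G06830 and AT2G47880 changed by -3.57 ± 0.71 and -3.53 ± 0.70 (adjusted p = 0.00543 and 0.00521). SAG101, a lipase-like gene of senescence and defence, rose by 1.61 ± 0.31 and STZ by 2.03 ± 0.46, and PRPL3 (AT2G43030) changed by -0.68 ± 0.10 (adjusted p = 0.00467, 0.0112 and 0.000469).

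Nuclear photosynthesis genes at 1 week on +P had 3 of 11 down and 0 up, PSAE-1, ATPC1 and LHCB4.1 with -0.47 ± 0.14, -0.45 ± 0.10 and -0.37 ± 0.11 (SE, n = 3 per group). When adjusted over the list alone 5 were down, with a median of -0.47 (camera adjusted p = 7.0e-05; adjusted p = 0.293 with an estimated correlation, 0.0256 by fry). The starch and sugar list had a median of -1.01 with 0 of 3 past the threshold and 2 lower when adjusted over the list alone (camera adjusted p = 0.0443; 0.106 after the filter on low values, and adjusted p = 0.293 with an estimated correlation, 0.0256 by fry). Senescence genes had a mean change of 1.07 with 1 of 4 up and 3 when adjusted over the list alone (camera adjusted p = 0.0443; adjusted p = 0.231 with an estimated correlation, 0.000477 by fry). The nitrate response regulator AT1G68670 (HHO2) changed by -1.05 ± 0.26 (adjusted p = 0.0200) with no camera call for its list (adjusted p = 0.106; 0.0448 by fry). Root markers, PYK10 among them, had none either (adjusted p = 0.152; 0.0249 by fry). The 1671 calls became 678 and 968 without WT replicates 2 and 3, 789 and 621 without pnp1-1 replicates 1 and 2. They became 1034 in a fit of the compared arrays alone, 1 with a block in that fit and 7902 with array weights. With 1 array left out at a time, PSAE-1, ATPC1, LHCB4.1, STZ and AT1G68670 lost their calls for 5, 1, 4, 2 and 3 of the 6 arrays (adjusted p up to 0.233, 0.0583, 0.225, 0.0732 and 0.132). PSAE-1 and LHCB4.1 also did so after the filter, quantile normalization or the trend. The other genes given here for this comparison passed without each single array, which was not so for all in the fits with fewer calls.

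After 1 week on -P, 250 probe sets were higher and 124 lower in pnp1-1. Among nuclear genes AT3G20370 was higher by 4.57 ± 0.71, AT2G32020 by 4.39 ± 0.29 and PYK10 by 2.24 ± 0.35 (SE, n = 3 per group; adjusted p = 0.00167, 5.6e-08 and 0.00159). The sugar transporters SWEET13 and SWEET4 changed by -4.06 ± 0.57 and -2.89 ± 0.52 and the expansin-like gene EXLB1 by -4.52 ± 0.68 (adjusted p = 0.000550, 0.00577 and 0.00124). APL4, a subunit of the starch-making enzyme ADP-glucose pyrophosphorylase, changed by -2.31 ± 0.40 (adjusted p = 0.00352). It was the 1 of 3 starch and sugar genes past the threshold, against 2 when adjusted over the list alone (mean change -1.54; camera adjusted p = 8.2e-05; adjusted p = 0.0941 with an estimated correlation, 0.00492 by fry). None of the 11 nuclear photosynthesis genes passed and 1 fell when adjusted over the list alone. The median was -0.31 (camera adjusted p = 9.0e-06; adjusted p = 0.147 with an estimated correlation, 0.0773 by fry). With the block 1 of them passed (0.0437 by fry), and 2 of the 3 starch and sugar genes. The nitrate list had a median of -0.43 with 0 of 3 past the threshold and 1 lower when adjusted over the list alone (camera adjusted p = 0.0403; 0.0655 with the block, 0.0866 by fry, and adjusted p = 0.147 with an estimated correlation). Of 23 mitochondrion-encoded probe sets, ccb382, of cytochrome c assembly, and cox1, of cytochrome c oxidase, rose by 2.23 ± 0.38 and 1.42 ± 0.33, with no call for the list of 23 (median 0.02; adjusted p = 0.0593). After the filter on low values 6 members were left, with a median of 0.81 and a camera call upward (adjusted p = 0.000442, 0.00128 by fry; adjusted p = 0.0766 with an estimated correlation). The 4 senescence genes had no camera call either (adjusted p = 0.0593; 0.0153 by fry), but did with the block (adjusted p = 0.0469; adjusted p = 0.135 with an estimated correlation). Cox1 lost its call without each of the arrays (adjusted p up to 0.126). The anthocyanin, sulfate and glucosinolate lists had 0 members past the threshold and no call in the 4 genotype comparisons. Lists for phosphate signalling, phosphate transporters, salicylic acid defence and floral transition had 0 measured members. The replicate numbers paired these arrays (correlations of 0.47 to 0.65). With the block over all arrays, also those that did not pair, 633 probe sets passed instead of 374. The count was 181 without WT replicate 3, 200 without pnp1-1 replicate 2, 52 in a fit of the compared arrays alone, 8 with a block in that fit and 3458 with array weights.

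**Figure D3:**
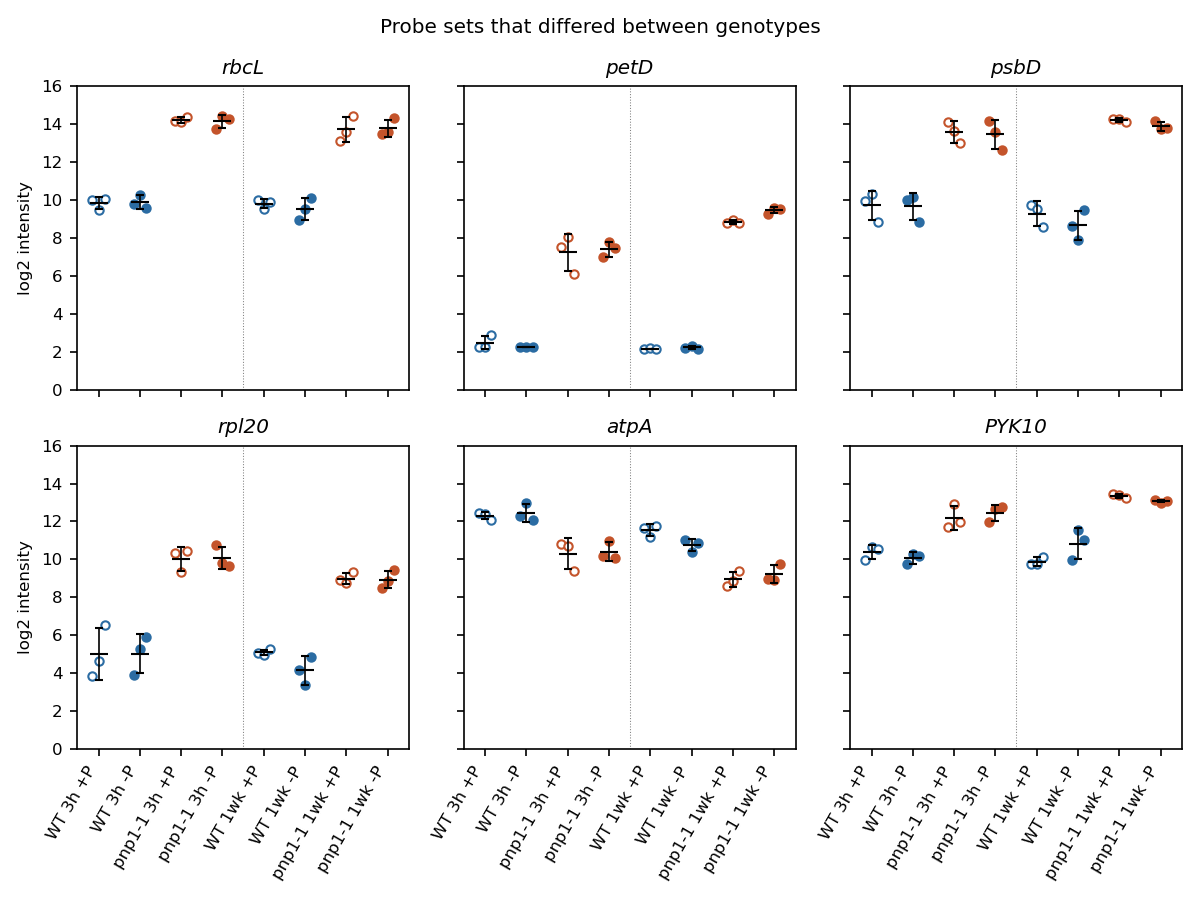
Log2 intensity (vertical axis) of 5 plastid-encoded genes and PYK10 on each of the 24 arrays, grouped along the horizontal axis by genotype, time and medium (open circles +P, filled circles -P; bars, group mean and SD, n = 3). On +P at 1 week rbcL stood at 13.71 ± 0.67 in pnp1-1 and 9.80 ± 0.23 in WT, and atpA at 8.94 ± 0.40 and 11.53 ± 0.31.

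Plastid-encoded transcripts, the substrates of PNPase, moved in both directions. Of 77 probe sets, 14 were higher and 11 lower in pnp1-1 at 3 h on +P, 15 and 7 at 3 h on -P, 14 and 13 at 1 week on +P, and 19 and 6 at 1 week on -P. Adjusted over the list alone these were 16 and 16, 18 and 11, 16 and 19, and 27 and 8. The cytochrome b6f gene petD was higher by 4.76, 5.14, 6.68 and 7.24 in these comparisons (SE 0.32 for each, n = 3 per group), from 2.15 ± 0.01 in WT to 8.83 ± 0.08 in pnp1-1 (SD, n = 3) on +P at 1 week. The large Rubisco subunit gene rbcL was higher by 4.36, 4.27, 3.92 and 4.27 (SE 0.33). The photosystem II core gene psbD was higher by 3.87, 3.80, 4.94 and 5.23 (SE 0.49), and rpl20, of the plastid ribosome, by 5.04, 5.03, 3.89 and 4.79 (SE 0.59), with adjusted p between 2.6e-10 and 0.000804 for these 4 genes. On -P at 1 week rps14 was higher by 5.40 ± 0.28 (adjusted p = 2.1e-09), but its change was as low as 0.71 among the 4 comparisons. Lower in the mutant, and chosen after their values were seen, were the ATP synthase gene atpA with -2.00, -2.03, -2.59 and -1.54 (SE 0.37) and the 4 genes psbE, psbF, psbL and psbJ of photosystem II. The changes were, for psbE, -1.25, -1.51, -1.31 and -1.08 (SE 0.18), for psbF, -0.82, -1.12, -1.19 and -0.94 (SE 0.11), for psbL, -1.08, -1.18, -1.24 and -0.80 (SE 0.16), and for psbJ, -1.34, -1.18, -1.08 and -0.76 (SE 0.15).

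As a list, plastid-encoded probe sets had a camera call in 1 genotype comparison, upward on -P at 1 week (median 0.40; adjusted p = 2.3e-14; adjusted p = 0.147 with an estimated correlation, 0.00337 by fry). In the other 3 the medians were -0.12, 0.05 and -0.04 (adjusted p = 0.951, 0.290 and 0.820). The means of 0.16 and 0.22 on +P at 3 h and 1 week had the opposite sign to the median and to the test's direction. Fry's p for change in either direction was 3.5e-27, 1.0e-21, 3.6e-27 and 5.1e-17. Without single arrays the calls of atpA, psbJ and psbL on -P at 1 week ended (adjusted p up to 0.182, 0.0566 and 0.0902), while those of the other plastid genes named here, and of these 3 in the other comparisons, passed.

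**Figure D4:**
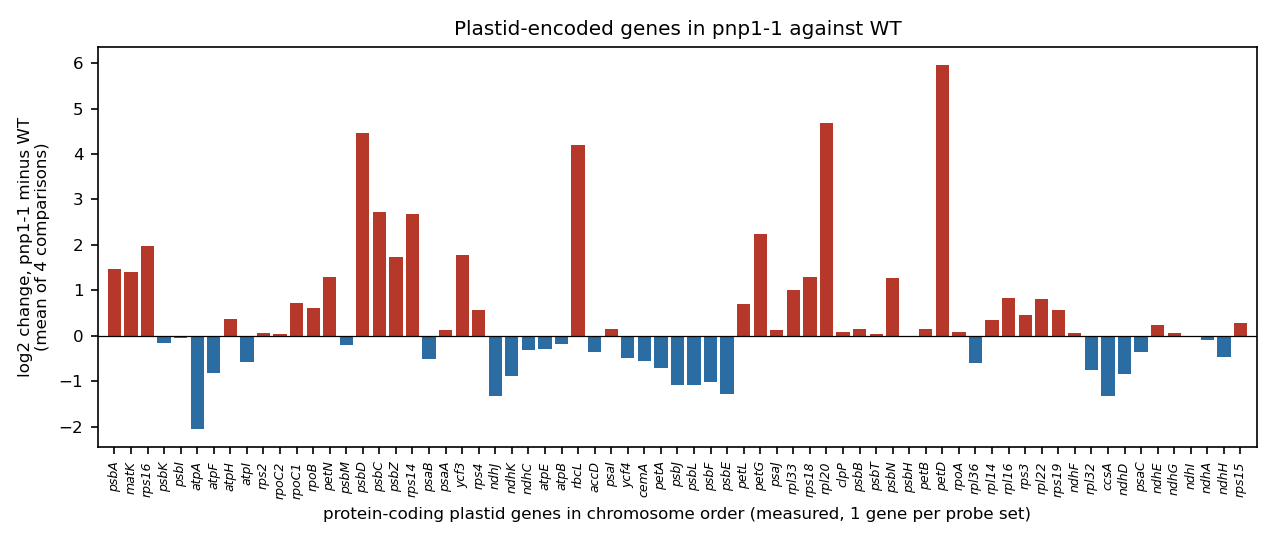
Mean log2 change in pnp1-1 against WT over the 4 genotype comparisons (vertical axis, 1 bar per gene, red for higher and blue for lower in pnp1-1) for protein-coding plastid genes in the order of the plastid chromosome (horizontal axis). Bars for psbE, psbF, psbL and psbJ stand side by side below 0, and petD has the tallest bar.

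The genotype by phosphate comparison asks whether the mutant responds to -P differently from WT. At 3 h limma called 0 probe sets, with an unadjusted p under 0.05 for 684. The smallest p belonged to AT5G15870 with a difference of -1.16 ± 0.19 (SE, n = 3 per group; adjusted p = 0.114). At 1 week 12 probe sets had a more positive and 6 a more negative change in pnp1-1. The response regulator RR16 differed by 2.12 ± 0.34, AT1G26410, of the berberine bridge enzyme family, by 2.12 ± 0.23 and AT1G68110 by 1.91 ± 0.31 (adjusted p = 0.0165, 0.000183 and 0.0197). AT5G09570, which rose in WT and already stood at 8.35 ± 0.36 in pnp1-1 on +P (SD, n = 3), differed by -4.54 ± 0.55, cwINV6 by -3.00 ± 0.32 and AT1G67330 by -1.87 ± 0.34 (adjusted p = 0.000824, 0.000183 and 0.0402). Plastid-encoded probe sets had a median difference of 0.53 (camera adjusted p = 2.2e-20; adjusted p = 0.124 with an estimated correlation, 0.0741 by fry), with 0 past the threshold and 3 up when adjusted over the list alone. Root markers had -0.15 (camera adjusted p = 0.00830; adjusted p = 0.252 with an estimated correlation, 0.0741 by fry) with 0 past the threshold on either adjustment.

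The count of 0 for genotype by phosphate at 3 h was 2 after quantile normalization, 1 with trend and robust settings, 4 with array weights and 3 with the block. It was 1 without WT +P replicate 1 or 2, and 2 without WT +P replicate 3, pnp1-1 +P replicate 1 or WT -P replicate 1. The 18 at 1 week became 3 in a fit of the 12 arrays of that time, 2 with a block there, and 2594 with array weights. It was 48 and 11 without WT +P replicates 1 and 2, 9 and 29 without pnp1-1 +P replicates 1 and 3, and 61 and 11 without pnp1-1 -P replicates 1 and 2. RR16, AT1G68110 and AT1G67330 lost their calls without single arrays (adjusted p up to 0.0719, 0.0739 and 0.166), AT1G67330 also did after quantile normalization or with the trend, and AT1G26410, cwINV6 and AT1G67330 did in the fit of the 12 arrays.

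Time by phosphate asks whether the response at 1 week differs from that at 3 h, set across separately normalized time points. In WT 91 probe sets had a more positive change at 1 week and 13 a more negative one. Among them were AT5G20790 with 7.80 ± 1.43 and AT1G08310 with 6.83 ± 0.86 (SE, n = 3 per group; adjusted p = 0.0125 and 0.000399). SWEET13 differed by 6.14 ± 0.80 and FHL by 5.45 ± 0.31 (adjusted p = 0.000560 and 2.1e-08), and the glutaredoxin AT3G62930 by -2.56 ± 0.44 (adjusted p = 0.00719). Plastid-encoded probe sets had a median of -0.58 (camera adjusted p = 6.6e-12; adjusted p = 0.274 with an estimated correlation, 0.135 by fry) and root markers 0.14 (camera adjusted p = 0.0293; adjusted p = 0.274 with an estimated correlation, 0.135 by fry), with 0 members of either past the threshold. In pnp1-1, 75 probe sets had a more positive and 8 a more negative change, with AT1G26390 at 7.31 ± 1.02, AT1G08310 at 6.78 ± 0.86 and FHL at 4.06 ± 0.31 (adjusted p = 0.00120, 0.000548 and 9.8e-07). NMT3 (AT1G73600) was at -4.85 ± 0.91 and cwINV6 at -2.29 ± 0.32 (adjusted p = 0.0230 and 0.00140). The count of 104 in WT was 207 without +P replicate 1 of 1 week, 45 with a block over the compared arrays and 957 with array weights. The 83 in pnp1-1 became 45 with that block, and 714 with array weights. They became 55 and 51 without 3 h +P replicates 2 and 3, 53 and 51 without 3 h -P replicates 1 and 3, and 45 and 51 without 1 week +P replicates 1 and 2. AT1G73600 lost its call without 8 of the 12 arrays (adjusted p up to 0.0746), AT5G20790, at 7.06 ± 1.43 (adjusted p = 0.0377), without 9 (up to 0.141), and AT1G22440, at -3.36, without 6 (up to 0.101).

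The responses were then set against each other across all 22746 probe sets, for 5 pairs of comparisons that share no array. Probe sets are not independent replicates, and the SE comes from leaving out each array, taken as unpaired. Groups of 1 time point can still share variation, since arrays of some groups paired by replicate number. On +P and -P at 3 h these correlations were 0.50 to 0.73 in WT and 0.24 to 0.46 in pnp1-1. Such shared variation can raise r and the overlaps without any effect, and its part was not tested. The phosphate responses of WT and pnp1-1 at 1 week correlated with r = 0.62 ± 0.17, but by rank only with 0.28. In both, 129 probe sets rose and 6 fell, where independent lists would share 3.46 and 0.441. Among the 859 probe sets past the threshold in either, 88.0% changed in the same direction. At 3 h r was -0.15 ± 0.28 (rank correlation -0.17), and r became 0.08 without pnp1-1 -P replicate 3. The genotype differences on +P and -P correlated with r = 0.78 ± 0.14 at 3 h (rank correlation 0.63). In both, 358 were higher and 242 lower, against 23.4 and 13.2 for independent lists. At 1 week r was 0.67 ± 0.14 (rank correlation 0.52), with 154 and 72 against 8.33 and 4.98. The response of WT to -P at 1 week correlated with the genotype difference on +P at 3 h with r = 0.26 ± 0.20 (rank correlation 0.15). In both, 81 probe sets rose and 59 fell, against 17.3 and 11.9 for independent lists. This r was 0.13 without 1 of the arrays and 0.33 without another.

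Pairs of comparisons that share a group correlate by construction, so the covariance was set against that of 50 simulations without effects. The WT response to -P at 1 week and the genotype difference on +P at 1 week, which share the WT +P arrays, had a covariance of 0.186 against 0.0518 in the simulations, with r = 0.51 against 0.47. In both, 137 probe sets rose and 172 fell where independent lists would share 14.1 and 14.4, an excess that may come in part from the shared arrays. Other pairs that share a group were simulated too. The WT response and the genotype difference on -P at 1 week had r = 0.03 against -0.54, with 24 up and 4 down in both and 31 opposite. The pnp1-1 response at 1 week and the genotype difference on +P had r = 0.01 against -0.49, with 18, 0 and 25. At 3 h the WT response and the genotype difference on +P had r = 0.54 against 0.53, with 0 called in WT. The simulations took the arrays as unpaired, and no spread of the excess over them was computed.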

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

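The tests of a larger plastid share, of neighbouring plastid genes, of changes already present in pnp1-1 on +P and of root tissue, the variance ratio with pnp1-1 paired, the margin asked of the count without 1 array, the leaving out of arrays and genes in the tests of present changes and neighbours, and the balanced splits were chosen only after the results were seen.

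Results are listed here because a test of the difference itself separated genotypes or time points; groups of 3 arrays were not tested for outliers. The genotypes differed in their response to -P at 1 week in 18 probe sets, among them RR16 (2.12), AT1G26410 (2.12), AT1G68110 (1.91), AT5G09570 (-4.54), cwINV6 (-3.00) and AT1G67330 (-1.87), and camera called the medians of root markers (-0.15) and plastid-encoded probe sets (0.53). Both list calls ended with an estimated correlation (adjusted p = 0.252 and 0.124) and by fry (0.0741 for both), with 0 members past the threshold. RR16, AT1G68110 and AT1G67330 lost their calls without 4, 4 and 9 of the 12 arrays (adjusted p up to 0.0719, 0.0739 and 0.166), and the 18 became 3 in a fit of the 12 arrays and 9 to 61 without 1 array. The response at 1 week differed from that at 3 h in 104 probe sets in WT, among them AT5G20790 (7.80), AT1G08310 (6.83), AT3G43110 (6.61), AT3G62930 (-2.56), AT1G68110 (-1.89) and AT5G42670 (-1.35), with camera calls for root markers (0.14) and plastid-encoded probe sets (-0.58). These calls too ended with an estimated correlation (adjusted p = 0.274 for both) and by fry (0.135 for both), with 0 members past the threshold. In pnp1-1 it differed in 83, among them AT1G26390 (7.31), AT5G20790 (7.06), AT1G08310 (6.78), AT1G73600 (-4.85), AT1G22440 (-3.36) and cwINV6 (-2.29). Of these AT5G20790, AT1G73600 and AT1G22440 lost their calls without 9, 8 and 6 of the 12 arrays (adjusted p up to 0.141, 0.0746 and 0.101).

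Plastid-encoded transcripts moved both ways in pnp1-1. A larger share of plastid RNA in the mutant would lift them together. On +P, 14.3% of them fell past the threshold at 3 h and 16.9% at 1 week, and on -P 9.09% and 7.79%. On -P at 1 week their median was 0.40, with a camera call upward. A common lift alone would give no such falls. A larger share beside falls of single genes is not excluded, and the falls were known when this test was chosen. A signal ceiling that keeps bright probe sets from rising stays open: the rank correlation of level with change was -0.20, with a bootstrap SD of 0.0994. Changes of neighbouring plastid genes correlated weakly, with 0.25 over 64 pairs (one-sided permutation p = 0.0193). Without psbE, psbF, psbL and psbJ, whose common fall had been seen, the correlation was 0.20 over 59 pairs (one-sided permutation p = 0.0496, at the edge of the threshold). Pairs such as petB and petD (0.16 and 5.96) moved apart. Neighbours were taken by gene order alone, without strand, so a pair need not share a transcript. The correlation therefore cannot decide on effects on shared transcripts, which stay open. Whether the amount of these RNAs or only their polyadenylated part differs was not tested and stays open too.

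More probe sets passed the threshold on -P at 1 week in WT than in pnp1-1 (781 and 214), also in a fit of the compared arrays (298 in WT) and with a block (1319 in WT), but with both the order turned (25 and 126), where the block joins WT arrays that did not pair by their numbers. A larger spread among the WT arrays stays open: the variance of changes beyond error was 2.46 times as large in WT (1.54 to 6.07 without 1 array), but 1.69 times with the pairs of pnp1-1 taken into account, 1.06 without WT +P replicate 2, and on the log2 scale 0.75 with a jackknife SE of 1.38. These pairs are uncertain, since only 2 of the pnp1-1 arrays correlated best with the array of their own number. A single deviating array stays open too, since the lowest count in WT without 1 array, 276 without +P replicate 2, lay little above the highest in pnp1-1, 253. Whether the changes of starved WT are already present in pnp1-1 on +P stays open as well: the 781 probe sets had a median of 0.20 at 3 h in the direction of the WT response, above an upper limit of 0.0733 from 10000 random lists, but such lists carry no variation between arrays, and leaving out arrays gave 0.06 to 0.34, with a jackknife SE of 0.183. No explanation of this pattern is argued against by the tables.

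PYK10 was higher in pnp1-1 in the 4 genotype comparisons. Root tissue left on the seedlings would raise other root markers with it, and the other 6 had a median change of 0.043 where PYK10 rose most, with 0 of them past the threshold in the 4 comparisons. Their highest level was 3.42 (PER57), while PYK10 lay at percentile 99.3, so such dim markers exclude nothing and root tissue stays open. A rise of PYK10 within the shoot was not tested and stays open too.

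The arrays of each comparison were also split in other ways. For comparisons of 3 arrays with 3 there are 10 splits, too few for a share under 0.05. The real and highest other counts were 0 and 228 for WT at 3 h (10 splits with as many), 781 and 226 for WT at 1 week (1 split), 2 and 34 for pnp1-1 at 3 h (5 splits) and 214 and 96 for pnp1-1 at 1 week (1 split). For pnp1-1 against WT they were 1686 and 37, 968 and 1, 1671 and 0, and 374 and 48 at 3 h on +P, 3 h on -P, 1 week on +P and 1 week on -P (1 split each). Where the replicate numbers pair the arrays, the other 3 splits that part all pairs gave at most 1 for WT at 3 h, pnp1-1 at 3 h and pnp1-1 at 1 week, 0 for pnp1-1 against WT on -P at 3 h and 2 on -P at 1 week.

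For the differences of differences, 100 splits of 12 arrays were drawn. Genotype by phosphate gave as many as the real count in 100 of them at 3 h (real 0, highest other 3539) and in 15 at 1 week (real 18, highest other 5297). Time by phosphate did so in 15 in WT (real 104, highest other 4927) and in 7 in pnp1-1 (real 83, highest other 3670). Chance cannot be excluded by these numbers, which decide little: a count of 0 is matched by any split, and many splits mix in the differences between genotypes, media or time points. The counts of the other 99 rose with the share of such a difference that a split takes up (rank correlations of 0.20, 0.34, 0.65 and 0.31). Among splits balanced for both differences, as many were called in 14 of 14, 1 of 19, 0 of 22 and 0 of 14, with highest counts of 8, 81, 3 and 2.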

How the results depend on the processing

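The fit of 1 time point, the block over the compared arrays alone and leaving out arrays for the correlations were chosen only after the results were seen.

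With a filter on low values, quantile normalization, or trend and robust settings, counts stayed within 1.5 times those reported, except where 2 or fewer were called. Array weights raised the counts. Both phosphate comparisons at 1 week went to 4068 (WT) and 2945 (pnp1-1), and that at 3 h in WT to 6. Genotype counts went to 2551 and 3197 at 3 h (+P, -P) and 7902 and 3458 at 1 week, genotype by phosphate to 4 at 3 h and 2594 at 1 week, and time by phosphate to 957 (WT) and 714 (pnp1-1). At 3 h in WT the count of 0 became 1 after quantile normalization and 1 with trend and robust settings, and that of genotype by phosphate 2 and 1. In pnp1-1 at 3 h the 2 calls became 0 with the filter on low values. The cause was not tested.

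With the replicate block, the counts were 4 (WT) and 1 (pnp1-1) at 3 h, 1319 in WT at 1 week, 2720 and 1585 for genotype at 3 h (+P, -P), 2529 and 633 at 1 week, and 3 for genotype by phosphate at 3 h. The block shared 763 of the 781 calls in WT at 1 week and 363 of the 374 for genotype on -P at 1 week. By their numbers the arrays did not pair in WT at 1 week or for genotype on +P. WT +P replicate 1 of 1 week varied with replicate 3 of the other 3 groups of that time (correlations of 0.55, 0.66 and 0.55) and had -0.56, -0.16 and -0.08 with their replicate 1. If its number was exchanged, the blocked counts that use these arrays join unrelated ones, whichever arrays are fitted. These are the counts for WT, genotype on +P and genotype by phosphate at 1 week, and time by phosphate in WT. The block fit of all arrays has 1 estimate of the spread. There the exchange would reach the other blocked counts, such as 633 for genotype on -P at 1 week and 1585 at 3 h. This was not tested.

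A fit of only the compared arrays has fewer residual degrees of freedom. It gave 298 in WT at 1 week, 0 in pnp1-1 at 3 h, 161 and 420 for genotype at 3 h (+P, -P), 1034 and 52 at 1 week, and 3 for genotype by phosphate at 1 week. With a block in that fit the counts were 25 in WT at 1 week, 0 in pnp1-1 at 3 h, 126 in pnp1-1 at 1 week, 0 and 145 for genotype at 3 h, 1 and 8 at 1 week, 2 for genotype by phosphate at 1 week, and 45 for time by phosphate in both WT and pnp1-1. A fit of only the arrays of the time point gave 0 in pnp1-1 at 3 h and 3 for genotype by phosphate at 1 week.

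Leaving out 1 array gave 1 to 17 (WT, 3 h), 276 to 1273 (WT, 1 week), 1 to 3 (pnp1-1, 3 h), 163 to 253 (pnp1-1, 1 week), 694 to 2172 and 425 to 806 (genotype at 3 h, +P and -P), 621 to 2113 and 181 to 459 (genotype at 1 week), 0 to 2 and 9 to 61 (genotype by phosphate, 3 h and 1 week), and 81 to 207 and 45 to 117 (time by phosphate, WT and pnp1-1).

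Of the list tests, 19 passed with camera's preset correlation, 0 with an estimated correlation, 13 with fry (9 of the 19 and 4 others), 14 after the filter and 20 with the block. After the filter 7 of the 10 lists were left, without root markers, sulfate and nitrate, which held 4 of the 19. The correlation of the phosphate responses at 1 week rose from 0.62 (0.28 by rank) to 0.82 among probe sets past the threshold in either genotype. Keeping only large changes can raise r by itself, so this rise is no sign of closer agreement. Without 1 array the correlation was 0.50 to 0.65. At 3 h it was -0.22 to 0.085 without 1 array, with the sign turned without pnp1-1 -P replicate 3. The other 3 correlations were 0.13 to 0.33 (WT at 1 week with genotype on +P at 3 h), 0.66 to 0.82 (genotype at 3 h) and 0.56 to 0.70 (genotype at 1 week).

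For the 220 results on single named genes, 3274 values under the alternatives held 2667 with the same call, 592 that no longer passed, 15 that newly passed and 0 that turned direction. Leaving out 1 array ended 257 of 1554, the compared arrays alone 105 of 220, with a block 166 of 220, and the arrays of the time point 35 of 190. With the replicate block 3 of 220 no longer passed, with the filter 6 of 210, with trend and robust settings 5, after quantile normalization 14 and with array weights 1.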

Other observations

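The list of genes induced by mitochondrial dysfunction was written, and its tests, with all or only the 5 members, chosen only after the results were seen, and gene families by symbol were added after the data were seen.

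Some genes induced by mitochondrial dysfunction were higher in pnp1-1. Of 18 genes of the list 9 were measured, with 4, 3, 7 and 5 of them past the threshold at 3 h on +P, 3 h on -P, 1 week on +P and 1 week on -P. At 3 h on -P, GSTU25 (-1.63) and HSP23.5 (-0.15) were lower, neither past the threshold. Other members were put on the list with their rise in view, so a test of all 9 decides nothing, and the 5 not named before were tested alone. They had 2, 1, 3 and 3 up and camera p of 2.2e-05, 0.0599, 1.8e-07 and 1.5e-09, so a rise of the list in all 4 comparisons stays open. These p are unadjusted and rest on the preset correlation of 0.01. An estimated correlation, 0.23 for all 9, was not used for the 5. In WT on -P the list had medians of 0.46 at 3 h and 1.1 at 1 week, with 0 and 1 of 9 past the threshold (camera p = 2.1e-06 and 0.000327; with an estimated correlation p = 0.010 and 0.0420), and the 5 members alone had 0 past the threshold (camera p = 6.0e-06 and 0.00262). In pnp1-1 at 1 week the median was 0.09 (camera p = 0.0307; with an estimated correlation p = 0.202). The cause of these changes was not tested.

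Gene families were tested as 27 groups of probe sets that share a symbol, and 0 passed the threshold with both the preset and the estimated correlation.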
